A study of Mus musculus with 9 samples.

How the data were processed

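Bulk RNA sequencing of sorted splenic Treg cells was analysed for 5 WT and 4 KO mice, 1 library per mouse. Total RNA was made into libraries with a stranded Illumina TruSeq kit, per the labels' protocols. The authors deposited 1 table of raw counts per gene symbol, whole numbers that sum to a different total in each library. The submitters' processing notes name STAR 2.7, DESeq2 and mm10, with no role stated. The counting program, gene annotation and strand setting are not given in the sources used here. Without them, reads shared by overlapping genes or by near-identical copies cannot be assigned with certainty, and 219 of the 414 called genes that could be placed overlap another annotated gene on either strand. Because no molecular identifiers are mentioned, intervals and floors (3 counts) cover counting error alone.

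Samples were grouped by their titles. All 9 columns of the table matched 1 sample each. Symbols were placed on mm10 with the GENCODE M21 annotation, 24746 by name and 618 through a RefSeq synonym, and 1319 were not placed. Total counts per library ran from 15269014 to 17425634, and genes that entered the test held 99.653% of the counts in WT 2 and more in each other library. No 2 libraries were duplicates, since a chi-square per degree of freedom over genes with a summed count of at least 10 was 2.66 for the closest pair and 32.7 for the most distant. Spearman correlations between libraries ran from 0.983 to 0.997.

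Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust dispersion, trimmed-mean scaling, default expression filter on the groups), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic. Log2 CPM values used a prior count of 2. On simulated counts for 12738 genes in 5 WT and 4 KO libraries, this test recovered 26% of 50 genes changed by 1.2-fold, 82% at 1.5-fold, 80% at 2-fold and 94% at 4-fold, and 3.43% of its calls were false. A total of 35 gene lists was fixed before the data were examined, of which 8 hold markers of other cell types. Lists with 5 or more tested genes, 33 in all, were tested with camera (limma 3.58.1, preset correlation 0.01), two-sided. On simulated lists 0 of 20 unchanged lists passed, although genes were simulated as independent. The mean level of each list per mouse, and shares of counts by gene class, were compared by two-sided exact permutation over the 126 splits of 9 libraries. The list of sex-linked genes had 1 tested gene, Xist.

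The rule for named genes was fixed in advance. It takes Esrrg, Foxp3, Il2ra, Ctla4 and Ikzf2, and the 12 genes higher and 12 lower in KO with the largest change among those past the threshold, with a mean CPM of at least 2 and no overlap between the groups. Unnamed gene models and antigen receptor segments were left out, and 17 and 1 of these were called. From each list it takes up to 4 called members by smallest p, or else the 2 members with the smallest p. The rule was met by 159 higher and 204 lower genes.

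Alternatives were other scalings, DESeq2 1.42.0, limma-voom with and without sample weights, other filters and thresholds, a surrogate variable (sva 3.50.0), replicate blocks, other set tests, and leaving out each library in turn. Leaving out KO 1 and KO 4 together, these and WT 1, or adding the level of plasma cell, neutrophil and macrophage markers as a covariate, were choices made after seeing the data.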

Results

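RNA was sequenced from splenic regulatory T cells (Treg cells), sorted as CD4-positive cells carrying a yellow fluorescent reporter of Foxp3, the transcription factor that defines this lineage. Each library came from 1 female mouse of 2 to 3 months, per the labels. The 5 control mice (WT) carried the Foxp3 reporter with Cre recombinase, and the 4 knockout mice (KO) carried in addition a floxed Esrrg gene. The bracketed library names begin with B6-N in every WT title and with Err in every KO title. If these names mark a difference of strain or colony, it cannot be told apart from genotype. Esrrg encodes estrogen-related receptor gamma, a nuclear receptor known for its control of mitochondrial genes, and the series title places it among lupus susceptibility genes. The comparison asks which transcripts of Treg cells differ when Cre is expressed with the floxed gene. Total counts ran from 15269014 in WT 4 to 17425634 in KO 1, so depth was similar in all 9 libraries. Of 26683 genes in the table, 2847 had no count in any library and 12738 entered the test.

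The targeted gene could not be used to check the labels. Esrrg (mm10, chromosome 1, 187608791 to 188214885, plus strand) had 0 counts in each of the 5 WT and 4 KO libraries. A count of 0 over all libraries together, KO included, allows up to 0.0206 CPM (count scaled to library size), counting error alone. The bound from the WT libraries alone is looser, and in single WT libraries 3 counts equal 0.178 CPM (WT 1) to 0.196 CPM (WT 4). A loss of Esrrg RNA was therefore not detectable at this depth. Its relatives were measured unevenly. Esrra had 500 to 624 counts per library and a log2 fold change (KO over WT) of -0.02 ± 0.06 (SE, n = 5 and 4, edgeR adjusted p = 0.875), whereas Esrrb summed to 2 counts and the coactivator gene Ppargc1a to 12 counts over all libraries. In the list of estrogen-related receptors and coactivators, 0 of 5 tested genes passed, with camera adjusted p = 0.577. The members with the smallest p were Pprc1, at -0.07 (edgeR adjusted p = 0.572), and Ppargc1b, at -0.11 (adjusted p = 0.721).

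The libraries differed from each other in more than genotype. The first principal component held 55.83% of the variance over the 500 most variable genes, and 42 of its 50 largest loadings were immunoglobulin genes. KO 4 lay at 42.6 and KO 1 at 21.7 on this axis, while KO 2 (-9.31) and KO 3 (-0.546) lay among or near the WT libraries (-18.5 to 1.11). The groups differed in position on it with exact permutation p = 0.0397 (two-sided, n = 5 and 4). Immunoglobulin genes took 0.798% of counts in KO 4 (95% Wilson interval 0.794 to 0.802) and 0.296% in KO 1 (0.293 to 0.298), against 0.119% ± 0.0194 (SD, n = 5) in WT. The share in KO was 0.343% ± 0.312 (SD, n = 4), with exact permutation p = 0.0238 and 0.0992 after adjustment over the 5 classes of genes compared. Mitochondrial genome genes took 1.65% ± 0.206 in WT and 1.63% ± 0.0921 in KO (exact p = 0.960). Cytosolic ribosomal protein genes took 4.96% ± 0.182 and 4.87% ± 0.122 (exact p = 0.405), haemoglobin genes 0.000714% ± 0.000484 and 0.000928% ± 0.000885 (exact p = 0.651), and the 10 most abundant genes 4.29% ± 0.0759 and 4.41% ± 0.0692 (exact p = 0.0397, adjusted 0.0992).

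**Figure D1:**
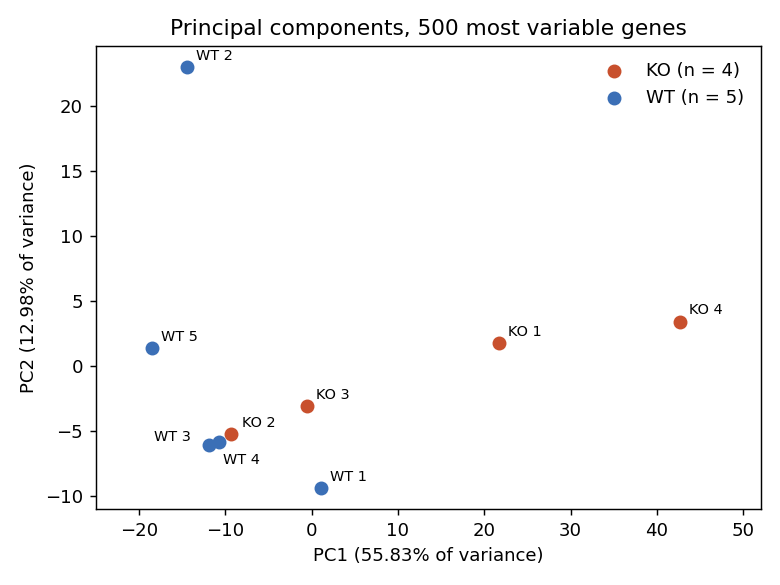
Each point is 1 library, placed by its first principal component (horizontal, 55.83% of variance) and its second (vertical, 12.98%), both in log2 CPM units over the 500 most variable genes. KO 4 and KO 1 lie at 42.6 and 21.7 on the horizontal axis, away from the other 7 libraries. WT 2 lies at 23.0 on the vertical axis, where the other libraries lie from -9.37 to 3.42.

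Xist, the RNA that coats the inactive X chromosome, was nearly absent from 1 library of this all-female series. KO 4 held 27 Xist counts against 27355 to 35693 in the other 8 libraries. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 2 counts in KO 4. Between the groups Xist had a log2 fold change of -0.39 ± 1.13 (SE, edgeR adjusted p = 0.877), and 0.019 without KO 4.

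**Figure D2:**
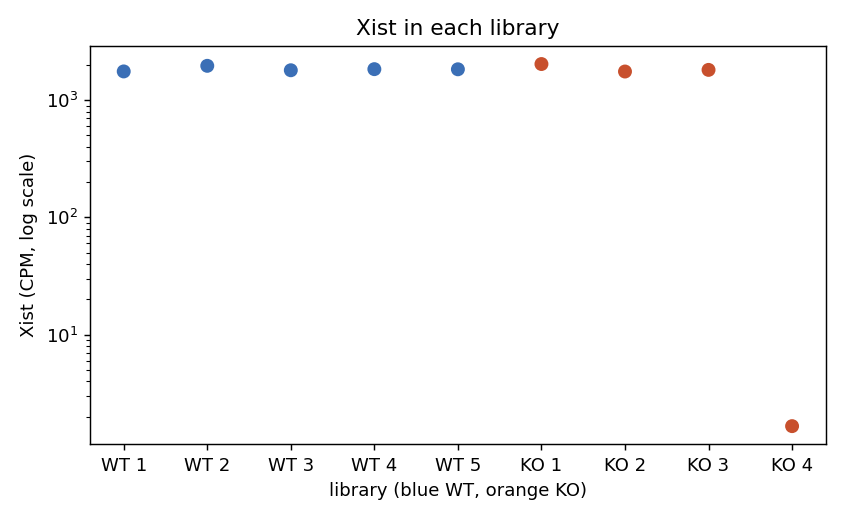
Each point is the Xist level of 1 library in CPM on a log scale, with 5 WT libraries in blue and 4 KO libraries in orange. The other 8 libraries lie between 1756 and 2034 CPM and KO 4 lies at 1.66 CPM.

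Differences between the KO and WT groups were small for most called genes. By edgeR's quasi-likelihood test, 418 genes passed a Benjamini-Hochberg adjusted p of 0.05, with 178 higher and 240 lower in KO, which is 3.28% of those tested. The median absolute log2 fold change of these genes was 0.29, and 74 changed by 1.5-fold or more, 25 up and 49 down. The WT and KO values did not overlap for 392 of the 418, which were picked by p in these same libraries. They did not overlap for 9.07% of all tested genes, against 1.59% by chance. The count depended on single libraries, falling to 97 without WT 3, 134 without WT 4, 117 without WT 5, 182 without KO 3 and 103 without the library labelled KO 4, and rising to 697 without WT 2. Without KO 1 and KO 4 together, a choice made after seeing the data, 118 genes passed.

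Gzmb, which encodes the cytotoxic protease granzyme B, showed the largest increase among the genes picked by size. It went from 4.17 ± 1.27 CPM (SD, n = 5) in WT to 12.1 ± 5.15 CPM (n = 4) in KO, a log2 fold change of 1.54 ± 0.31 (SE, edgeR adjusted p = 0.0334). Its highest values were in KO 1 (18.8 CPM) and KO 4 (13.6 CPM), and without these libraries its log2 fold change was 0.94 (adjusted p = 0.0926). The Gzmb call also ended without WT 1, WT 3, WT 4, WT 5 or KO 4 alone. Ide, the insulin-degrading enzyme (chromosome 19, 37268743 to 37337852), had the most uniform increase, from 107 ± 5.47 to 204 ± 11.2 CPM, a log2 fold change of 0.93 ± 0.05 with adjusted p = 1.35e-06. Cfl2, encoding the actin-binding protein cofilin 2, rose from 23.2 ± 3.67 to 44.7 ± 4.16 CPM (log2 fold change 0.95, adjusted p = 0.00323). Myl4, a myosin light chain gene, rose by 1.21 on the log2 scale (adjusted p = 0.0107) and Fam81a by 0.93 (adjusted p = 0.0401). On chromosome 18, Ammecr1l (31759826 to 31782743) rose by 0.66, the RNA polymerase II subunit gene Polr2d (31789159 to 31796701) by 0.75 and Sft2d3 (31909098 to 31911824) by 0.76, with adjusted p of 0.0414, 0.0102 and 0.00899. Syne2, which encodes a nuclear envelope protein, rose by 0.66 (adjusted p = 0.0272) and Xkr6 by 0.66 (adjusted p = 0.0393). The transcribed pseudogene Tmem181b-ps rose by 1.26 (adjusted p = 0.00106), and its count is uncertain because it resembles other Tmem181 copies.

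Among the genes that fell, Rell1, a relative of the tumour necrosis factor receptor family member RELT (chromosome 5, 63908897 to 63968897), went from 24.6 ± 1.28 to 8.32 ± 1.05 CPM, a log2 fold change of -1.56 ± 0.09 (SE, edgeR adjusted p = 1.94e-06). Carns1, which encodes carnosine synthase (chromosome 19, 4164324 to 4175479), went from 109 ± 7.24 to 58.8 ± 3.76 CPM (log2 fold change -0.89, adjusted p = 7.37e-06). Erdr1 changed by -1.18 (adjusted p = 0.022), Cybrd1, a ferric reductase gene, by -1.15 (0.0143) and the phosphoinositide phosphatase gene Synj2 by -0.89 (0.00767). The axonemal dynein gene Dnah17 changed by -1.04 (0.0018), the netrin gene Ntn4 by -0.9996 (0.00899) and the neuropilin gene Nrp2 by -0.92 (0.0258). Kcnh3, a potassium channel gene, Poln, a DNA polymerase gene, Epb4.1l1 and the troponin gene Tnnt2 had log2 fold changes of -1.07, -1.07, -1.06 and -0.93, with adjusted p of 0.018, 0.0196, 0.0102 and 0.0204. All 24 genes picked by size passed under the 3 other scalings and by DESeq2, 12 passed in every fit that left out 1 library, and 12 passed without KO 1 and KO 4. Counting the members of lists named below, 48 named genes were called and 15 of them passed in every fit that left out 1 library. Among these 48, Acadvl, Gpx1 and Hsp90ab1 passed in 1 of the 9 such fits, and Ammecr1l, Mrpl21, Mrps16, S100a10, Hsp90aa1 and Bak1 in 2. Of the 24, 17 overlap another annotated gene, and the strand setting of the counting is not given in the sources used here, so reads of the partner gene may be included.

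**Figure D3:**
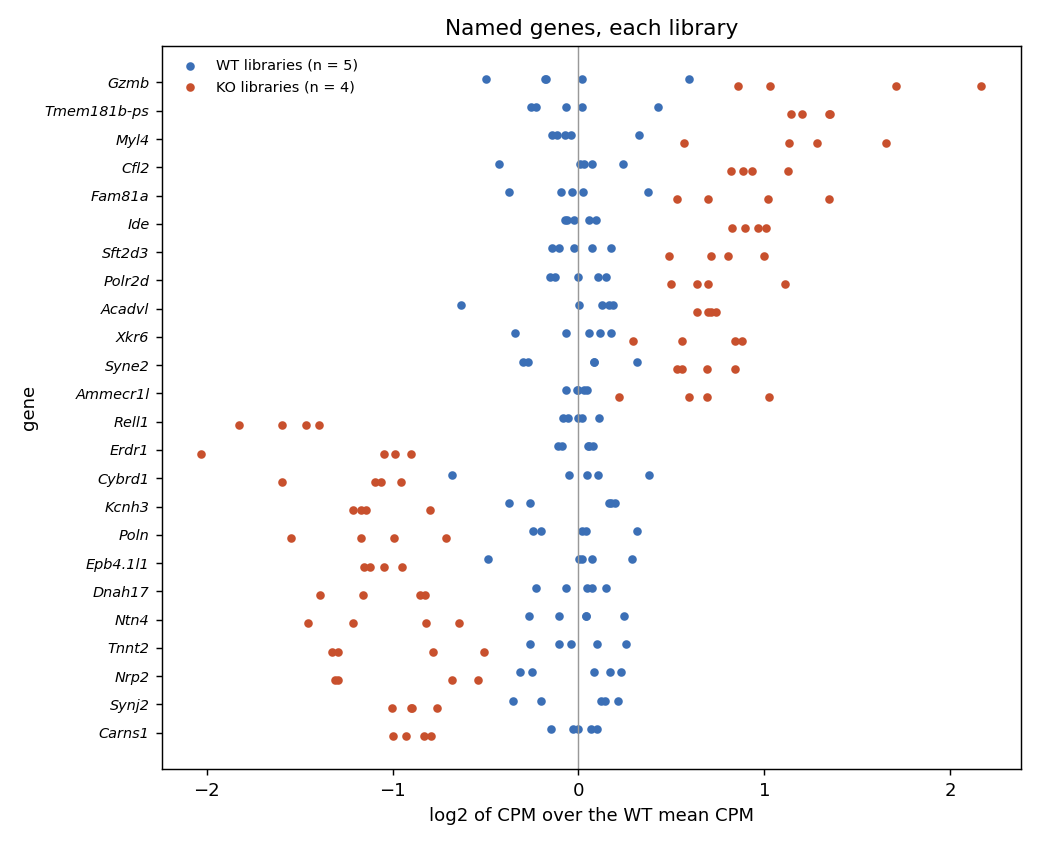
Each point is 1 library, with its CPM over the WT mean CPM on a log2 scale (horizontal) for the 12 genes with the largest increase and the 12 with the largest decrease (vertical), WT in blue (n = 5) and KO in orange (n = 4). The KO points lie wholly to 1 side of the WT points for each gene, as the rule that picked them requires. The genes run from Gzmb (log2 fold change 1.54) to Rell1 (-1.56).

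The genes that define Treg identity did not pass the test. Foxp3 itself was at 574 ± 25.9 CPM (SD, n = 5) in WT and 575 ± 31.7 CPM (n = 4) in KO, a log2 fold change of 0.0027 ± 0.047 (SE, edgeR adjusted p = 0.980) whose sign flipped with upper-quartile scaling (-0.0016). Il2ra, the alpha chain of the interleukin-2 receptor, was at 846 ± 76.6 and 749 ± 38.9 CPM (log2 fold change -0.18, adjusted p = 0.146). Ctla4, an inhibitory receptor, was at 419 ± 103 and 409 ± 55.7 CPM (-0.04, adjusted p = 0.931), and Ikzf2, which encodes Helios, at 1019 ± 31.0 and 1009 ± 67.3 CPM (-0.01, adjusted p = 0.898). In the core Treg list 0 of 25 genes passed, and 0 when adjusted over the list alone (camera adjusted p = 0.383). The member with the smallest p was Cd5, at 0.13 (adjusted p = 0.0549). T cell receptor signalling genes also had 0 of 22 past (camera adjusted p = 0.276), with Nfatc1 at 0.21 (adjusted p = 0.0995) and Cd28 at 0.09 (adjusted p = 0.133). This list passed without KO 1 and KO 4 (camera adjusted p = 0.0113), without WT 1 as well (0.00613) and with 1 surrogate variable (0.0385). In the interleukin-2 and STAT5 list 1 of 14 genes passed, against 1 higher and 1 lower when adjusted over the list alone. That gene was the anti-apoptotic Bcl2, which changed by -0.35 (adjusted p = 0.026), while the list did not pass (camera adjusted p = 0.240).

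Nuclear genes for oxidative phosphorylation, the mitochondrial ribosome and fatty acid oxidation were slightly higher in KO as lists, with few members past the test singly. Of the 77 nuclear genes for subunits of oxidative phosphorylation, 73 had a positive log2 fold change, with a median of 0.08, and 2 passed singly, 3 when adjusted over the list alone. These were Atp5f1 (0.19, edgeR adjusted p = 0.0243) and Cox7a2 (0.22, adjusted p = 0.0325), subunits of ATP synthase and of cytochrome c oxidase. The list passed with camera adjusted p = 2.29e-07, but not with an estimated correlation between genes (adjusted p = 0.556 with an estimated correlation). Its mean went from 0.08 to 0.05 without KO 1 and KO 4, and its level in WT 2 (5.72) lay above KO 2 (5.70) and KO 3 (5.68). Mitochondrial ribosome genes had 63 of 75 positive and a median of 0.10, with Mrpl21 (0.22, adjusted p = 0.0368) and Mrps16 (0.23, adjusted p = 0.0482) past and 0 when adjusted over the list alone. Their camera adjusted p was 2.39e-06, and adjusted p = 0.556 with an estimated correlation. The transcripts in these 2 lists are short, with a median length of 1410 bases against 3220 for all tested genes, taking the longest annotated transcript of each gene. The joint median log2 fold change of the 2 lists went from 0.09 to 0.026 when the trend of fold change with this length was removed. Fatty acid oxidation genes had 2 of 20 past, 4 when adjusted over the list alone. Cpt1a, the gate of fatty acid import into mitochondria, went from 61.5 ± 3.74 to 84.8 ± 9.20 CPM (0.46, adjusted p = 0.00682), and Acadvl, the dehydrogenase for very long chains, from 49.99 ± 10.2 to 81.1 ± 2.43 CPM (0.70, adjusted p = 0.0461). This list passed with camera adjusted p = 0.0302 (adjusted p = 0.556 with an estimated correlation). Its call ended without KO 1 (0.0594) or without KO 4 (0.133), and its adjusted p was 0.437 without both. Cpt1a (chromosome 19, 3322334 to 3385733) lies near Mrpl21 (3282901 to 3292837), so these 2 calls may not be separate.

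Genes encoded by the mitochondrial genome itself did not pass with all libraries. In their list 0 of 7 passed (camera adjusted p = 1.0), with a median of 0.011, a mean of -0.0016, mt-Nd1 at -0.07 (edgeR adjusted p = 0.787) and mt-Cytb at 0.04 (adjusted p = 0.825). Without WT 1, KO 1 and KO 4 this list passed in the higher direction, with camera adjusted p = 0.00613. The tricarboxylic acid cycle list had 0 of 21 past (camera adjusted p = 0.085), with Pdk1 at -0.29 (adjusted p = 0.0753) and Pdk3 at 0.19 (adjusted p = 0.106). Mitochondrial biogenesis and dynamics had 0 of 25 past (camera adjusted p = 0.982), with Polg2 at -0.25 (adjusted p = 0.125) and Pink1 at -0.43 (adjusted p = 0.227). In glycolysis 1 of 20 genes passed, the lactate dehydrogenase gene Ldha, which rose from 400 ± 20.8 to 467 ± 10.8 CPM (0.22, adjusted p = 0.0183), and the list did not pass (camera adjusted p = 0.0593). It passed without WT 2 (0.0128), with the bracketed library number as a replicate block (0.0104) and with cameraPR on the edgeR statistic (0.043). Adjusted over the list alone, 3 glycolysis genes were higher and 2 lower. Antioxidant genes had 2 of 20 past, 3 when adjusted over the list alone, the glutathione reductase gene Gsr (0.26, adjusted p = 0.0469) and Gpx1 (0.22, adjusted p = 0.0488), with camera adjusted p = 0.0126 (adjusted p = 0.556 with an estimated correlation). Without KO 1 and KO 4 the antioxidant list had camera adjusted p = 0.305. Its mean went from 0.06 to -0.08, although the set test kept the higher direction. Cholesterol synthesis had 0 of 23 past, 1 when adjusted over the list alone (camera adjusted p = 0.718), with Ebp at 0.25 (adjusted p = 0.0525) and Stard4 at 0.17 (adjusted p = 0.0878).

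Lists of activated and suppressive Treg genes were higher in KO, most of all in KO 1 and KO 4, and the libraries overlapped. WT 2 lay above KO 2 and KO 3 in the level of suppressive genes (5.13 against 4.96 and 5.08) and of effector Treg genes (6.21 against 6.05 and 6.15), and WT 1 lay above all 4 KO libraries in helper T cell effector genes (3.42 against 3.20 to 3.39). Of 20 suppressive effector genes, 5 rose and 6 when adjusted over the list alone. They included Il1rl1, the interleukin-33 receptor, from 25.0 ± 2.90 to 36.0 ± 2.89 CPM (0.53, edgeR adjusted p = 0.00899), the inhibitory receptor gene Pdcd1 (0.42, adjusted p = 0.0204) and the costimulatory receptor gene Icos (0.31, adjusted p = 0.0231), besides Gzmb. The list passed with camera adjusted p = 0.00138 (adjusted p = 0.556 with an estimated correlation). The mean log2 fold change fell from 0.33 to 0.10 without KO 1 and KO 4, with camera adjusted p = 0.0429. Effector Treg genes had 3 of 25 past and 11 when adjusted over the list alone, among them S100a10 (0.25, adjusted p = 0.0374), with camera adjusted p = 1.03e-05 (adjusted p = 0.556 with an estimated correlation) and 0.0683 without KO 1 and KO 4, or 0.0145 when WT 1 was left out as well. Resting T cell genes passed in the lower direction with camera adjusted p = 0.0105 (adjusted p = 0.556 with an estimated correlation). Bcl2 alone passed among their 17 genes, against 6 lower and 1 higher when adjusted over the list alone. Their call ended without KO 1 (0.0681) or KO 4 (0.0755), and the mean turned to 0.04 without both. Helper T cell effector genes passed as a list (camera adjusted p = 0.0176, adjusted p = 0.556 with an estimated correlation) with 0 of 10 genes past, Tnf at 0.21 (adjusted p = 0.093) and Il12rb1 at 0.24 (adjusted p = 0.129). Without KO 1 and KO 4 their adjusted p was 0.0900, and without WT 1 as well it was 0.0133. Their call also ended at a mean CPM of at least 5 (0.082) and with the marker level as a covariate (0.1305).

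Several receptors and regulators changed in lists that did not pass. The follicular list had 2 of 16 past, Pdcd1 and Bcl6, which encodes the transcriptional repressor that directs follicular T cells and which rose from 47.3 ± 3.20 to 58.1 ± 3.20 CPM (0.30, edgeR adjusted p = 0.0204), and 2 when adjusted over the list alone, with camera adjusted p = 0.240 and 0.0326 without KO 2. Among homing receptors 2 of 20 passed, and 7 higher and 1 lower when adjusted over the list alone. These were Gpr183, an oxysterol receptor, which rose from 66.6 ± 5.20 to 92.4 ± 7.50 CPM (0.47, adjusted p = 0.00478), and Cxcr6 (0.61, adjusted p = 0.0349), with camera adjusted p = 0.131, 0.0453 without KO 2 and 0.0374 with cameraPR. Immediate early genes had 1 of 24 past, 1 when adjusted over the list alone, Egr2 (0.29, adjusted p = 0.0368), and camera adjusted p = 0.168 in the lower direction, with a mean of -0.73. With the title number as a replicate block the list passed in the lower direction (camera adjusted p = 0.0173). Without WT 1 the direction turned higher (adjusted p = 0.651). WT 1 stood apart there, with a mean log2 CPM of 7.98 against 6.05 to 6.45 in the other WT libraries. Interferon-stimulated genes had 1 of 21 past, 2 when adjusted over the list alone. That gene, Gbp2, rose from 116 ± 8.81 to 143 ± 8.62 CPM (0.30, adjusted p = 0.0203), with camera adjusted p = 0.0642 for the list. The list passed without WT 4 (1.36e-05), without KO 1 (0.00956), without KO 4 (0.0355), without KO 1 and KO 4 together (0.000571) and without WT 1 as well (0.00613). It also passed with 1 surrogate variable (0.000849), with the marker level as a covariate (0.0146) and at a mean CPM of at least 5 (0.0477). Among apoptosis regulators 2 of 14 passed, Bcl2 and the pro-apoptotic Bak1 (0.21, adjusted p = 0.046), against 1 higher and 2 lower when adjusted over the list alone, with camera adjusted p = 0.301.

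Stress and proliferation genes also leaned upward. Heat shock genes had 2 of 9 past, 5 when adjusted over the list alone, with Hsp90ab1 from 1471 ± 120 to 1721 ± 53.2 CPM (0.23, edgeR adjusted p = 0.046) and Hsp90aa1 at 0.36 (adjusted p = 0.0469). The list passed with camera adjusted p = 0.0137 (adjusted p = 0.556 with an estimated correlation), and its call ended without KO 2 (0.0772). In the stress and unfolded protein response list 3 of 16 passed, 5 when adjusted over the list alone, namely Sdf2l1 (0.64, adjusted p = 0.0208), the serine synthesis gene Psat1 (0.39, adjusted p = 0.0262) and Xbp1 (0.25, adjusted p = 0.0324). Its camera adjusted p was 0.042 (adjusted p = 0.556 with an estimated correlation) and 0.124 without KO 1 and KO 4. Its call also ended without WT 2 (0.0548), WT 3 (0.0539), KO 1 (0.0594), KO 2 (0.0595) or KO 4 (0.0657) alone. Cell cycle genes were all positive, 33 of 33, with a median of 0.93, and 0 passed singly, 3 when adjusted over the list alone. Their level in WT 2 (4.91) lay above KO 2 (4.30) and KO 3 (4.56), with exact permutation p = 0.0794. Ccne2 was at 0.93 (adjusted p = 0.0581) and Mcm4 at 0.27 (adjusted p = 0.0613). The list passed with camera adjusted p = 8.13e-10 (adjusted p = 0.556 with an estimated correlation), and its mean fell from 0.78 to 0.17 without KO 1 and KO 4 (adjusted p = 0.00976). Cytosolic ribosomal protein genes had 0 of 79 past and a median of -0.03 (camera adjusted p = 0.058), with Rps27l at 0.32 (adjusted p = 0.0549) and Rps4l, an annotated pseudogene, at 1.08 (adjusted p = 0.0842). That list passed in the lower direction under the 3 other scalings (0.0487 with RLE), at a mean CPM of at least 5 (0.0388) and without WT 3 (0.00385), WT 5 (0.00158) or KO 2 (0.00173). Its direction turned higher without KO 1 and KO 4 (0.778), with the marker level as a covariate (0.871) and with 1 surrogate variable (0.889).

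Plasma cell, neutrophil, dendritic cell and monocyte and macrophage markers were highest in KO 1 and KO 4, and in WT 1 they were the highest of the WT libraries for plasma cell (2.17), monocyte and macrophage (2.62) and dendritic cell markers (2.93, against 3.00 in KO 1). Mean log2 CPM of plasma cell markers was 2.66 in KO 1 and 4.63 in KO 4, against 1.27 ± 0.574 (SD, n = 5) in WT, and that of neutrophil markers 2.26 and 2.96 against -0.43 ± 0.724. In the plasma cell list 0 of 5 passed, with Jchain at 2.33 (edgeR adjusted p = 0.185) and Derl3 at 1.53 (adjusted p = 0.115), and the camera adjusted p was 0.0398. In the neutrophil list 0 of 6 passed, with Mpo at 3.67 (adjusted p = 0.163) and Mmp9 at 0.90 (adjusted p = 0.120), and the camera adjusted p was 0.0235. Dendritic cell markers had 0 of 6 past (camera adjusted p = 0.0154), with Cd74 at 0.80 (adjusted p = 0.142) and Zbtb46 at 0.52 (adjusted p = 0.199). For these 3 lists the value was adjusted p = 0.556 with an estimated correlation. Monocyte and macrophage markers had 0 of 12 past (camera adjusted p = 0.0137, adjusted p = 0.558 with an estimated correlation), with Fcgr3 at 1.29 (adjusted p = 0.108) and Cybb at 0.47 (adjusted p = 0.175). Without KO 1 and KO 4 the adjusted p values of these 4 lists were 0.652, 0.652, 0.437 and 0.778 in that order, and the mean of the last turned to -0.16. Dendritic cell markers passed when WT 1 was left out as well (0.00613), and the other 3 lists did not. Each of the 4 calls also ended without KO 1 alone (0.0666, 0.065, 0.0594 and 0.065) or KO 4 alone (0.109, 0.0802, 0.0623 and 0.122). The first 3 ended without WT 2 as well (0.0898, 0.081 and 0.0548), and the plasma cell call without WT 4 (0.0573) or WT 5 (0.0572). With the bracketed library number as a replicate block the plasma cell call ended too (0.104).

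The remaining marker lists did not pass. B cell markers had 0 of 7 past (camera adjusted p = 0.254), with Cd79b at 0.24 (edgeR adjusted p = 0.204) and Cd22 at 0.19 (adjusted p = 0.312), but the list passed without KO 2 (0.0453) or KO 3 (0.0176). CD8 T and natural killer markers had 0 of 6 past, 1 when adjusted over the list alone (camera adjusted p = 0.301), with Gzma at 2.08 (adjusted p = 0.0763) and Eomes at -0.18 (adjusted p = 0.505). Erythroid and platelet markers had 0 of 5 past and camera adjusted p = 0.624 in the lower direction, although their median was 0.40 and their mean 0.32, with Itga2b at -0.32 (adjusted p = 0.216) and Hba-a2 at 0.92 (adjusted p = 0.459). They passed in the lower direction without KO 1 and KO 4 (0.0429). Stroma and endothelium markers, with 2 tested genes, were too few for the set test, with Col1a1 at 0.48 (adjusted p = 0.218) and Col1a2 at -0.40 (adjusted p = 0.518).

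In all, 15 of 33 lists passed by camera with a preset correlation, 14 higher and 1 lower in KO. Among these 15, the fatty acid oxidation list alone had levels that did not overlap between the groups (5.31 to 5.35 in WT and 5.39 to 5.50 in KO). Among the lists that did not pass, homing receptors (at most 6.412 in WT, at least 6.422 in KO) did not overlap either. Nor did apoptosis regulators (at least 6.142 in WT, at most 6.135 in KO). With an estimated correlation 0 passed (smallest adjusted p = 0.556, and 0 lists at an unadjusted p under 0.05). By fry for a shift in 1 direction 0 passed (smallest adjusted p = 0.143, with 10 lists at an unadjusted p under 0.05). Fry for members changed in either direction asks another question. Its adjusted p ran from 0.00028 for fatty acid oxidation to 0.975 for estrogen-related receptors and coactivators. Tested as a mean level per mouse by exact permutation (two-sided, smallest possible p = 0.00794), 0 of 35 lists passed, with a smallest adjusted p = 0.139 and 8 lists at an unadjusted p under 0.05. The fatty acid oxidation and homing receptor lists both reached the smallest possible p, and their adjusted p was still 0.139. With 9 libraries and adjustment over 35 lists, this test could hardly pass a list, so its count of 0 says little.

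**Figure D4:**
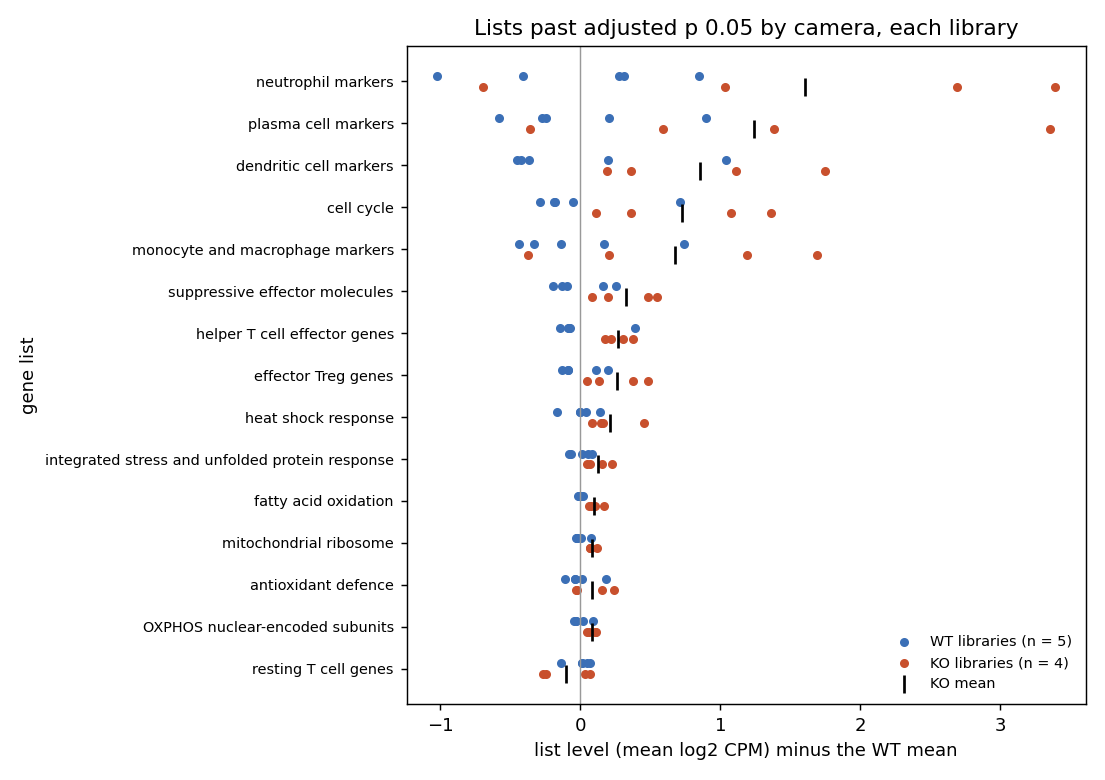
Each point is 1 library, with the mean log2 CPM of a gene list minus the WT mean (horizontal) for the 15 lists past camera's adjusted p of 0.05 (vertical), WT in blue (n = 5), KO in orange (n = 4) and the KO mean as a black bar. Plasma cell and neutrophil markers spread most within KO (SD 1.58 and 1.83), and the oxidative phosphorylation list differed by 0.08 between the group means.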

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

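The tests on Xist, on the heat shock genes alone, on chromosomal position and on DNA near Esrrg were chosen after their results were seen. The tests on RNA of other cells rest on leaving out KO 1 and KO 4, which was also chosen after seeing the data, and the tests on transcript length and other splits were not. Of 140 groups of 4 or 5 values examined for a sample far from the rest, 16 had one, where chance gives about 1 in 20, or 7.

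The library labelled KO 4 had a mean of 0.831 log2 CPM for the 1 tested sex-linked gene, against 10.8 in the nearest KO library, because its Xist level was 1.66 CPM against 1756 CPM. A male mouse or a swap with a male sample is argued against by the 2 Y-linked counts in this library. A fault limited to Xist reads is argued against by genes known to escape X inactivation, whose median difference from the other KO libraries was -0.43 on the log2 scale over 7 genes, 5 of them below every other library. Kdm6a stood at 84.3 CPM against at least 149 CPM elsewhere, while the other 399 X-linked genes had a median difference of -0.0033. The escape genes lay below 100% of 10000 random sets of X-linked genes of like expression, which is consistent with most cells of that mouse having no inactive X chromosome, and whether this arose in the animal or in its T cells stays open.

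WT 1 lay far from the other WT libraries in several lists. Its immediate early genes had a mean of 7.976 log2 CPM (nearest other WT library 6.454), its helper T cell effector genes 3.415 (2.949), its mitochondrial genome protein genes 10.07 (9.742) and its cholesterol synthesis genes 4.993 (5.091). Its share of counts in mitochondrial genome genes was 2.008% (1.621%). WT 2 stood apart in glycolysis with 6.479 (6.339), the core Treg list with 7.694 (7.56), resting T cell genes with 7.713 (7.86) and cell cycle with 4.907 (4.136), and in single genes with 3.031 CPM of Myl4 (2.357) and 32.31 CPM of Acadvl (50.11). WT 4 had an interferon-stimulated level of 6.143 (5.637), KO 1 a homing receptor level of 6.719 (6.472), and KO 2 a Kcnh3 level of 1.669 CPM (1.313).

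A signal also appeared in counts that no comparison used. WT 2, labelled female, held 23 counts of the 4 Y-linked genes, against at most 3 in any other library, with an Xist count of 32399 within the range of the others.

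The largest number of called genes in any 5 Mb window was 9, which 0.4902 of random placements reached or passed. In 1 Mb windows it was 5, which 0.7118 of placements reached or passed, so by these counts chance placement stays open. A scan that weighs windows by their tested genes, run after that result, picked out chromosome 12 from 72085589 to 76921412, where 9 of 25 tested genes were called, with permutation p = 0.0005, the smallest that 2000 placements can give, or 0.0015 after multiplying by the 3 scans run. There 3 genes were higher (Jkamp, Trmt5, Syne2) and 6 lower (Dhrs7, Prkch, Snapc1, Sgpp1, Churc1, Fntb). Without KO 1 and KO 4 the 9 fold changes kept a median of 0.976 of their size (0.816 to 1.17), so they did not rest on these libraries alone. Calls made with all libraries favour genes alike in every KO library, so this ratio cannot decide on RNA of other cells as a cause. DNA linked to the floxed gene lies on chromosome 1, where 7 of 160 tested genes within 20 Mb of Esrrg were called (4.38% against 3.29% elsewhere, Fisher exact p = 0.3758), which neither shows nor excludes it. Carried DNA of another strain on chromosome 12 may give such a cluster and was not tested. The 1 Mb window with 5 called genes, on chromosome 19 from 3282901 to 4175479, held Mrpl21, Cpt1a, Cdk2ap2, Pitpnm1 and Carns1 among 29 tested genes. On chromosome 18 from 31759826 to 31911824, 4 of 12 tested genes were called, all higher (Ammecr1l, Polr2d, Wdr33 and Sft2d3). Whether such neighbours changed for a shared reason was not tested, so they need not be separate results.

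Other splits of the 9 libraries were compared with the genotype. For single genes, 1 of 100 splits, the real one, gave as many as 418 genes, and the highest other gave 30. This is the smallest share that 100 splits can give, which argues against chance for the count without excluding it. Every other split mixes WT and KO libraries within a group, which widens the spread there. The splits also cannot tell genotype from another difference between the groups. For gene lists, 19 of 100 splits gave as many as 15 lists and the highest other gave 18, so chance is not excluded for the number of lists.

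The lists that were higher in KO followed KO 1 and KO 4 in part. Over the 10 lists that are not cell markers, the median ratio of the mean log2 fold change without these libraries to that with all was 0.450 (-1.40 to 1.38), and 0.535 with the marker level as a covariate, where oxidative phosphorylation kept 0.875 and mitochondrial ribosome genes 0.907. RNA of plasma cells and myeloid cells in KO 1 and KO 4 therefore stays open for part of the lists, although the sort on CD4 and the Foxp3 reporter is meant to remove such cells and leaving these mice out would also remove a true activation of their Treg cells. For heat shock genes the ratio was 1.38 (1.15 to 1.95 in list level leaving out each other library), which argues against that source, and their highest level was in KO 2, without which the list did not pass (0.0772). For the oxidative phosphorylation and mitochondrial ribosome lists, removing the trend with transcript length left 0.3001 of their median, but cytosolic ribosomal protein genes, which are shorter still (median 1059 bases against 1410), had a median of -0.03, so a length bias cannot be told apart from a change of these genes, and an effect of the Esrrg genotype stays open.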

How the results depend on the processing

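Fits without KO 1 and KO 4, without these and WT 1, and with the marker level as a covariate were chosen after seeing the data. All 418 genes kept their direction in every fit that contained them. This follows largely from their selection in the same libraries, where the groups did not overlap for 392 of them, so it adds little support. The number of genes past the threshold (418, with 178 higher and 240 lower) changed between fits. It was 888 (444 and 444) with DESeq2, 781 (375 and 406) with limma-voom and sample weights, 21 (7 and 14) against a fold of 1.2, 61 (20 and 41) at an adjusted p under 0.01, and 981 (445 and 536) under 0.1. It was 43 (13 and 30) with 1 surrogate variable, 118 (45 and 73) without KO 1 and KO 4, 250 (98 and 152) without WT 1, KO 1 and KO 4, and 83 (26 and 57) with the marker level as a covariate. Leaving out each library in turn gave 97 to 697 genes, 32 to 335 higher and 64 to 362 lower, with fewer samples in each such fit. Apart from the replicate blocks, given below, the other alternatives stayed within 1.5 times, from 341 without robust dispersion to 522 with a mean CPM of at least 5. Fewer samples or a stricter threshold account for part of these changes by construction, and for the others the cause was not tested.

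A replicate block by title number left 26 genes (12 higher and 14 lower), and a block by the bracketed library number 443 (232 and 211). Whether these numbers mark litters or batches is not known. Deviations of same-numbered libraries correlated at 0.099, -0.062, 0.1 and -0.067 by title and at 0.099, 0.087, 0.057 and -0.26 by library number. Not every library correlated best with its own number. These correlations show no pairing of the mice, but they cannot exclude a shared litter or batch.

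The number of lists (15) was 6 with 1 surrogate variable, 8 without KO 1 and KO 4, 11 without WT 1 as well and 7 with the marker level as a covariate. It was 0 with an estimated correlation and 0 by fry for a shift in 1 direction. Leaving out each library gave 9 to 17, with 9 without KO 1 and 9 without KO 4. The cause was not tested. With 1 surrogate variable the adjusted p was 0.468 for fatty acid oxidation, 0.368 for antioxidant defence, 0.101 for suppressive effector molecules, 0.942 for resting T cell genes, 0.0827 for effector Treg genes, 0.216 for helper T cell effector genes, 0.138 for integrated stress and unfolded protein response and 0.733 for dendritic cell markers. Under the same fit interferon-stimulated genes (0.000849) and T cell receptor signalling (0.0385) passed. The mean of the resting T cell list turned to 0.042 without KO 1 and KO 4 and to 0.062 without WT 1 as well. The mean of the list antioxidant defence turned to -0.08 without KO 1 and KO 4 and to -0.018 with the marker level as a covariate. The set test kept the higher direction for this list in these fits. With 1 surrogate variable the plasma cell list turned to -0.32 and the monocyte and macrophage list to -0.30, and the neutrophil list was lower by the set test although its mean was 0.13. The monocyte and macrophage list was also at -0.16 without KO 1 and KO 4 and at -0.17 with the marker level as a covariate. For the variation among samples, the first principal component held 63.09% of the variance over 100 genes and 47.37% over 2000.

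Genes that changed sign were not past the threshold. Leaving out each library gave gene Ikzf2 -0.056 to 0.020, gene Ctla4 -0.14 to 0.11, gene Foxp3 -0.023 to 0.034, gene mt-Nd1 -0.13 to 0.052, gene mt-Cytb -0.0074 to 0.11 and gene Xist -0.63 to 0.019. The gene Ctla4 was at 0.059 with limma-voom and sample weights and at 0.015 with the library number as a replicate block. The gene Foxp3 was at -0.0016 with upper-quartile scaling, -0.00031 with a mean CPM of at least 5 and -0.0031 with the title number as a replicate block. With 1 surrogate variable gene Pprc1 was at 0.034, gene Jchain at -0.043, gene Mpo at -0.48, gene Hba-a2 at -0.46 and Xist at 0.41. Without KO 1 and KO 4, Pprc1 was at 0.014, Ppargc1b at 0.030, mt-Nd1 at 0.0057, Mpo at -0.32 and Hba-a2 at -0.98. Without WT 1, KO 1 and KO 4, gene Ppargc1b was at 0.11, mt-Nd1 at 0.13 and Mpo at -0.076. With the marker level as a covariate, Pprc1 was at 0.012, Mpo at -0.24, Hba-a2 at -0.38 and Xist at 0.21. With limma-voom and sample weights mt-Nd1 was at 0.047. The cause of these changes was not tested. Depth limits the lowest genes, where 3 counts equal 0.172 to 0.196 CPM per library.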

Other observations

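The values of 2 genes were picked after they were seen. Slc15a2, which encodes a peptide transporter, was at 123.9 CPM in WT 3 and 139 CPM in KO 3, between 7.41 and 25.9 CPM in the other libraries except KO 4, and at 0.797 CPM in KO 4. Erdr1, annotated near the pseudoautosomal boundary of the sex chromosomes in mouse, was between 40.6 and 46.3 CPM in WT, between 21.2 and 23.4 CPM in KO 1, KO 2 and KO 3, and at 10.7 CPM in KO 4, the library nearly without Xist.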
